A study of Mus musculus with 8 samples.

How the data were processed

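Poly(A) RNA was sequenced from injured mouse tibialis anterior with extensor digitorum longus, collected 3 days after injection of notexin at 2 mg/mL. The sources disagree on whether stem cells sorted from these muscles or the muscles themselves were used. Notexin is a snake venom phospholipase that destroys muscle fibres and leaves their stem cells to rebuild them. The labels give 8 libraries, 4 of the group Ctrl and 4 of the group Psat1iKO, with no further factor. The labels name muscle stem cells sorted by flow cytometry as the cell type, while the series' design text describes Trizol extraction of RNA from the muscles themselves. The deposited values carry no record of which material each library holds. The low counts of blood, vessel and immune cell genes given in the Results argue against unsorted muscle. No profile of unsorted muscle was compared. Nothing in the labels says that the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

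Per the submitters' processing notes, HISAT2 2.2.1, DESeq2 (listed as version 4.2.0) and the mouse genome build mm10 were used by the authors. The program that counted reads, the gene annotation, filters, strand setting and adapter trimming are not given in the sources used here. Libraries were made from 250 ng of RNA with the NEBNext Ultra II kit, per the labels.

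The authors' deposited table of the comparison holds 36743 rows for 16573 gene symbols, of which 8131 have more than 1 row and the highest number for 1 symbol is 23. Names such as Psat1 and Psat1.1 show that rows are finer than genes, and they are treated here as transcript-like parts of a gene that cannot be matched to a specific isoform. Each row gives the authors' mean of DESeq2-normalized counts over all libraries (a signal averaged over the 8 libraries, lowest value 2.22), a log2 fold change with its standard error, a Wald statistic (a score equal to the fold change divided by its error) and the authors' p-value with its adjusted p. The deposited adjusted p equals Benjamini-Hochberg adjustment over the listed rows to within 1.39e-05. The deposited log2 fold changes are coded as Ctrl over Psat1iKO, per the file headers, and were turned to Psat1iKO minus Ctrl here. That sign was checked on Eno1b, which is among the genes of the deposited enrichment for genes higher in Psat1iKO. The other deposited tables are lists of enriched terms for rows higher and lower in Psat1iKO, with the authors' log10 of the enrichment p and q, which were converted to p and q.

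No values per library were analysed here. The sequencing depth of each library is therefore unknown, no SD between libraries can be given, and the error printed for a row is the authors' DESeq2 standard error. The mean normalized counts sum to 37005033 over all rows, which is a mean over libraries and not the depth of any of them. The test fixed before the data were examined for this case, the authors' own adjusted p under 0.05, was used for rows, with and without an absolute log2 fold change of at least 1. A count test, another normalization, a pseudocount, leaving out libraries, a replicate block, other splits of the libraries and set tests with an estimated inter-gene correlation all need values per library and were not run.

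Group means were rebuilt from the pooled mean and the fold change, assuming equal group sizes and comparable libraries, and are called fitted means. Rows of 1 gene were summed on this scale to give a gene total, which has no test. The row with the highest mean count of a gene is called its leading row. This choice was made after the table was seen, because the rows were finer than the planned tests assumed. A row with an adjusted p under 0.05 in the authors' DESeq2 comparison is said to be called, and Benjamini-Hochberg adjustment over the leading rows alone gives a count per gene.

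For gene lists, 29 lists of pathways, states and cell types were fixed before the data were examined. They were tested on the Wald statistics of the leading rows with cameraPR of limma 3.58.1 (R 4.3.3), two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists with at least 5 measured members. The alternatives were preset correlations of 0, 0.05 and 0.2, a rank version, a mean of at least 100 and every row of each gene. A last alternative dropped Eno1 and Eno1b from all leading rows tested. Eno1 is a member of the glycolysis list and Eno1b of none. The test sets a list against all tested rows, so the extreme statistic of Eno1b enters the result of every list.

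Named genes follow a rule fixed before the data were examined: Psat1 first, then per direction the 12 called rows of highest absolute fold change among rows with a mean of at least 100 and a standard gene symbol, up to 4 members of smallest p per list, and a set of serine pathway and myogenic genes. Genes and rows named outside this rule were chosen after their values were seen. These are Acaca, Scd1, Dhcr7, Cdkn1a, Mbnl3, Padi2, Ndufs5, Tnfrsf1b, Hmgn2, Zfp985, Tpm1.11, Myh11.2 and the minor row of Pmp22. Others are the leading rows of Mtor and Tsc1, and Egr1, Tlr3, Sema6c, Sema4g, Tsc2 and Ulk1 from the deposited terms. In the closing observations they are Strn4, Cdc27, Kirrel, Xpnpep1 and the sex-linked genes. The values of 1 list member are not reported here.

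Gene positions come from a RefSeq table of GRCm38.p6, the same assembly as mm10, in which 16477 symbols were found and 96 were not. Odds ratios have exact conditional 95% confidence intervals. Transcripts of Eno1 and Eno1b were aligned with blastn 2.17.0. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

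The row test was tested on simulated data that used the deposited standard errors of all 36743 rows, with 200 rows of mean at least 100 changed. It recovered 13.4% of rows changed by 0.25 on the log2 scale, 40.1% at 0.5, 64.8% at 1 and 83.0% at 2. The list test, run on 16573 simulated gene statistics with 5 lists shifted by 1 SD, recovered 93.0% of shifted lists and called 0.429% of the unshifted ones. These simulated statistics were independent of each other and held no extreme row such as Eno1b. The 2 shares therefore do not give the power or error rate of the list test on the real statistics.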

Results

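The data are RNA profiles from mouse hindlimb at 3 days after notexin injury, in a group labelled Psat1iKO and a group labelled Ctrl, with n = 4 libraries in each. The labels name sorted muscle stem cells and the design text names the muscles themselves as the source of RNA. Psat1 encodes phosphoserine aminotransferase, which makes phosphoserine from phosphohydroxypyruvate and glutamate in the serine biosynthesis pathway. The series' title names this pathway in muscle regeneration, and the comparison asks which transcripts differ between the genotypes at this time. Genes of the muscle stem cell and myoblast list were abundant, with a median mean normalized count of 2057 over 25 measured members. The median was 306 for adult myofibre genes, 84.6 for monocyte and inflammatory macrophage genes, 25.3 for endothelial genes and 6.01 for neutrophil genes. It was 1089 for adipocyte genes, of which 10 of 20 were measured. Of these, Fasn, Scd1 and Acaca are also in the cholesterol and fatty acid synthesis list. Extracellular matrix genes had 619, fibro-adipogenic progenitor and fibroblast genes 294, and pericyte and smooth muscle genes 230. Erythroid genes stood at 9.91 and T and NK cell genes at 7.92. Blood, vessel and immune cell genes thus lay far below muscle stem cell and myoblast genes, which argues against unsorted muscle as the source. No profile of unsorted muscle was compared, and adipocyte and extracellular matrix genes were not as low. Library depth is unknown, since the authors' deposited table gives only a mean over all 8 libraries for each row.

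Psat1 lies on chromosome 19 from 15905123 to 15925059 in GRCm38. Its leading row, Psat1.1, had a mean normalized count of 17283 and was lower in Psat1iKO in the authors' deposited table, with a log2 fold change of -0.49 ± 0.0675 (SE) and a DESeq2 adjusted p of 1.22e-09. That is a fold of 0.711, so most of the Psat1 signal remained. The minor row Psat1, with a mean count of 76.5, had a log2 fold change of 0.68 ± 0.514 and an adjusted p of 1 by DESeq2 in the authors' deposited table. Fitted means summed over both rows were 20262 in Ctrl and 14456 in Psat1iKO. The labels do not say which exons are removed, and reads from exons that remain count towards these rows.

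The other serine pathway enzymes were not called. Phgdh, which catalyses the first step of serine synthesis, had a log2 fold change of 0.02 ± 0.0383 in the authors' deposited table, and Psph, the phosphatase of the last step, had -0.10 ± 0.143. The leading rows of the serine and glycine hydroxymethyltransferases Shmt1 and Shmt2 stood at 0.00 ± 0.114 and -0.03 ± 0.0725 in the authors' deposited table, and the mitochondrial folate enzyme Mthfd2 at 0.01 ± 0.0776. Of 24 measured genes of serine synthesis and folate one-carbon metabolism, Psat1 alone was called (1 lower, 0 higher), also when adjusted over the list alone. The list as a whole did not pass the test (limma cameraPR adjusted p = 0.575).

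Across the authors' deposited table, 241 rows of 231 genes passed a DESeq2 adjusted p of 0.05, 122 higher and 119 lower in Psat1iKO. With a change of at least 2-fold in addition, 177 rows of 171 genes remained, 91 higher and 86 lower. Most of these were minor rows of genes with several rows. The median called row past 2-fold had a mean count of 33.6 and held 5.42% of its gene's total, and only 18 of the 177 were leading rows. An absolute log2 fold change of at least 6 was found in 133 of the 177. On rows of low mean, a change of that size leaves very few counts in 1 group, so its exact size is loosely set. Of the 171 that belonged to genes with more than 1 row, the summed rows of the gene changed 2-fold for 3. This held for 9 of all 177, where a gene with 1 row counts by definition, since its total is the row itself. The leading rows of well-measured genes differed little: over 10260 leading rows with a mean of at least 100, the median log2 fold change was -0.01, and 92.6% had a 95% interval inside a 2-fold change.

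**Figure D1:**
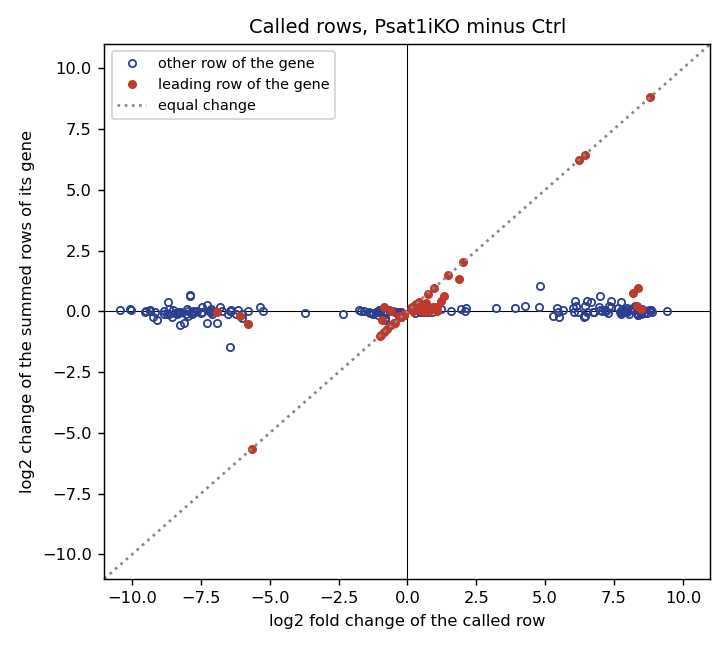
Each point is 1 of the 241 called rows, with its log2 fold change (Psat1iKO minus Ctrl) on the x axis and the log2 change of the summed fitted means of its gene on the y axis. Filled points are leading rows, open points are other rows of the gene, and the dotted line marks equal change. Most rows far from 0 on the x axis lie near 0 on the y axis.

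The lower rows of highest fold change belonged to genes whose totals were almost level. In the authors' deposited table, Zswim8 had a log2 fold change of -10.42 ± 1.24 on a row with 2.95% of the gene's total, with a DESeq2 adjusted p of 3.59e-13. Plec.1, of the cytoskeletal linker plectin, stood at -8.34 ± 1.43 in the authors' deposited table with 0.187% of the total. A minor row of the growth regulator kinase Mtor, Mtor.1, had -7.47 ± 0.88 with 3.01% of the total, while the leading row Mtor stood at 0.04 ± 0.0512 in the authors' deposited table. Tsc1.6, a row of an inhibitor of the Mtor pathway, had -3.72 ± 0.683 with 10.2% of the total, while the leading row Tsc1.2 had 0.27 ± 0.19 in the authors' deposited table. The others of the 12 were Secisbp2l.1, Zfp869.2, Dnmt1.1, Pbx3, Rere.4, Pals2, Tnks1bp1 and Pcnx.2, of which Rere.4 lost its call among rows with a mean of at least 100 (adjusted p 0.0539). None of the 12 was a leading row and for 0 of them did the gene total change 2-fold.

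Of the 12 higher rows, 8 were leading rows. Eno1b, a copy of the glycolytic enolase gene Eno1, was highest with a log2 fold change of 6.24 ± 0.0473 in the authors' deposited table, where its DESeq2 adjusted p is listed as 0. Tut4, a terminal uridylyltransferase, had 1.86 ± 0.509 with a DESeq2 adjusted p of 0.042 in the authors' deposited table, which became 0.0527 among rows with a mean of at least 100 and 0.0831 over leading rows alone. Ak1.3, of adenylate kinase, had 1.34 ± 0.358 and Smad6, an inhibitor of BMP signalling, 1.20 ± 0.321 in the authors' deposited table (DESeq2 adjusted p 0.032 for both, and 0.0638 for both over leading rows alone). Padi3, which converts arginine to citrulline in proteins, had 0.97 ± 0.151 with a DESeq2 adjusted p of 1.33e-07 in the authors' deposited table. Pphln1.4, Sytl2.4, Rev3l.3, Phf12.3, Gabpb1.1, Zkscan8.2 and Pld1 made up the rest. Zkscan8.2 also lost its call over leading rows alone (adjusted p 0.0771), and Pphln1.4 among rows with a mean of at least 100 (0.0539). The gene total changed 2-fold for Eno1b and Tut4 among these 12.

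Eno1 and Eno1b moved in opposite directions by nearly equal amounts. Eno1 lies on chromosome 4 from 150236708 to 150248879, and Eno1b on chromosome 18 from 48045335 to 48048379. From the authors' deposited table, the fitted mean of Eno1 fell from 119773 in Ctrl to 85252 in Psat1iKO (log2 fold change -0.49 ± 0.0281, DESeq2 adjusted p 8.97e-64). That of Eno1b rose from 427 to 32157. Their sum was 120200 in Ctrl and 117410 in Psat1iKO, a log2 change of -0.03 ± 0.0236 (propagated SE). The transcripts share 99.5% of 1652 aligned bases, so reads that cover none of the 9 mismatches fit both over this stretch, and the division of counts between the 2 rows is uncertain.

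**Figure D2:**
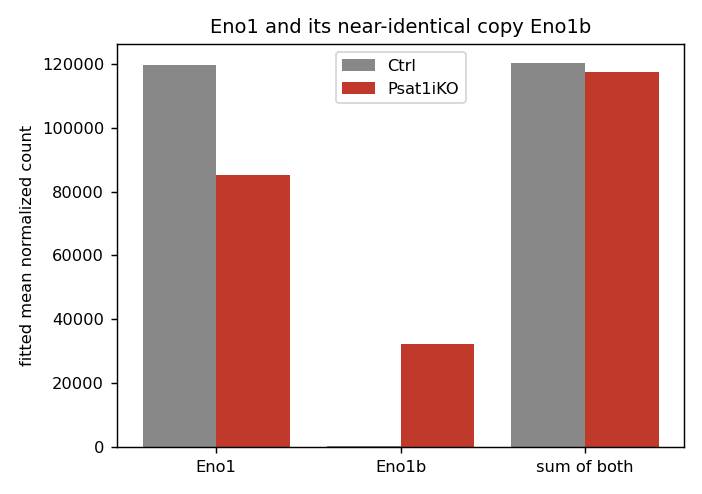
Bars give the fitted mean normalized count of Eno1, of Eno1b and of their sum, in Ctrl (grey) and Psat1iKO (red), without error bars because no values per library were used. The sum differs by -0.03 on the log2 scale while Eno1b alone differs by 6.24.

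With Benjamini-Hochberg adjustment over the leading rows alone, 37 genes were called, 20 higher and 17 lower, and 11 of them changed at least 2-fold. Myod1, which encodes a transcription factor of myoblast commitment, was among them at a log2 fold change of 0.16 ± 0.0386 (DESeq2 adjusted p 0.0058 in the authors' deposited table). The muscleblind splicing regulator Mbnl3 was also among them, named here after its value was seen, at 0.56 ± 0.0769 in the authors' deposited table. Of 37 called genes, 15 lay within 20 Mb of Pax7 on chromosome 4, where 474 genes were measured, and 22 among 16003 genes elsewhere. The odds ratio was 23.7 (95% interval 11.4 to 48.2, Fisher's exact test two-sided p = 3.22e-14), over a window set after the genes were seen and with genes that are not independent of each other. Eno1, Padi2, Padi3, Ndufs5, Tnfrsf1b and Hmgn2 are in this window, with 5 of its called genes higher and 10 lower. Within 20 Mb of Psat1 on chromosome 19, Psat1 was the 1 called gene of 343.

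**Figure D3:**
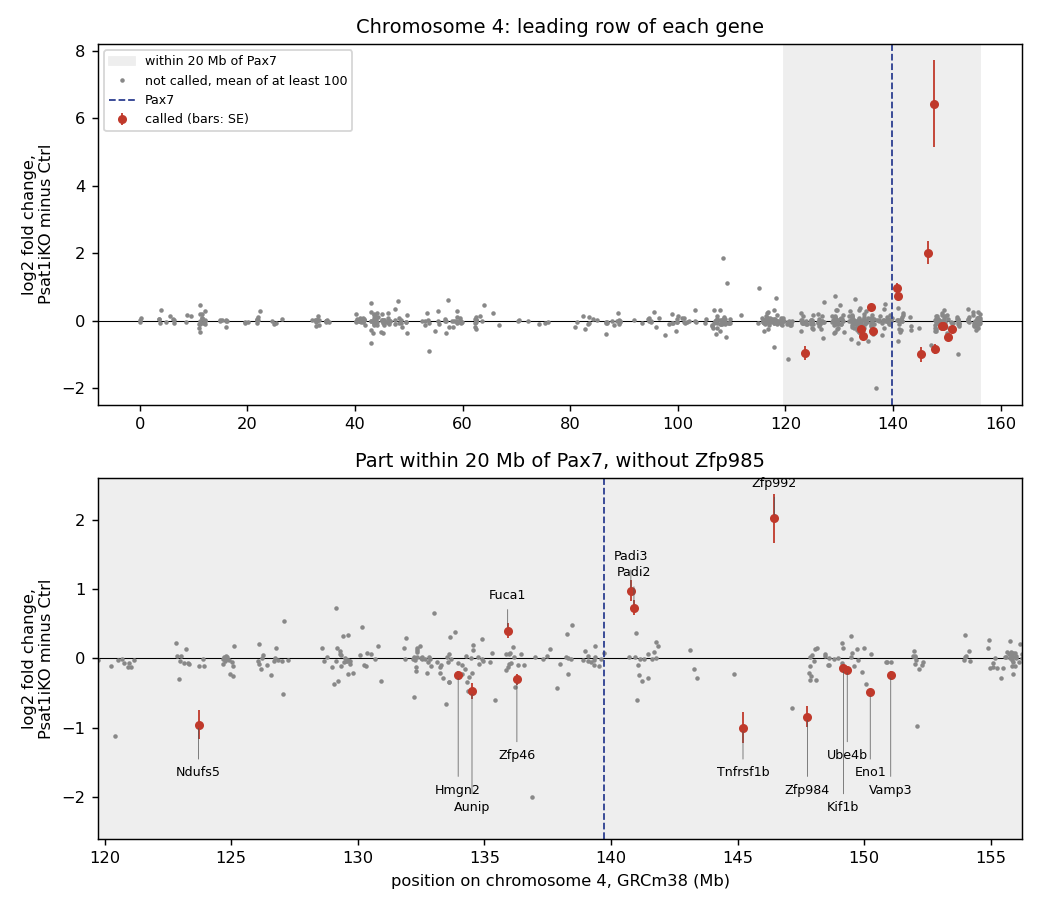
Log2 fold changes (Psat1iKO minus Ctrl) of the leading row of each gene are plotted against position on chromosome 4 in GRCm38, in Mb, with the whole chromosome above and the part within 20 Mb of Pax7 (shaded) below. Grey points are genes not called over leading rows alone that have a mean of at least 100. Red points are the 15 genes called over leading rows alone, with their SE, and the dashed line marks Pax7. Of the called genes, Zfp985 (log2 fold change 6.43 on a mean count of 8.21) lies outside the range of the lower panel.

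Genes of cholesterol and fatty acid synthesis, the targets of the SREBP transcription factors, were lower in Psat1iKO as a group. Of 26 measured members, 24 had a log2 fold change under 0, with a median of -0.21 (limma cameraPR adjusted p = 9.19e-06). No member was called over all rows (0 of 26), and 10 were lower against 1 higher at an unadjusted p under 0.05. The count adjusted over the list alone is not reported for this list. Sqle, which makes squalene epoxide, had -0.22 ± 0.0882 and Idi1, an isomerase of the isoprenoid steps, -0.35 ± 0.149 in the authors' deposited table. Members of highest value were Dhcr7 at 0.77 and Acaca at 0.14 in the authors' deposited table. At a preset correlation of 0.05 the list's adjusted p was 0.00393, and at 0.2 it was 0.551. The macrophage lists were lower and the pericyte list higher in the same comparison, with 0 leading rows called in each. At a preset correlation of 0.05 each of those lists had a limma cameraPR adjusted p of 0.0798.

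Targets of p53, a transcription factor of the DNA damage response, were higher in Psat1iKO as a group. Of 20 measured members, 15 lay above 0, with a median of 0.13 (limma cameraPR adjusted p = 0.00815), and the adjusted p was 0.0798 at a preset correlation of 0.05. Zmat3, an RNA-binding protein, rose by 0.27 ± 0.067 and Ccng1, cyclin G, by 0.26 ± 0.0694 on the log2 scale in the authors' deposited table, with DESeq2 adjusted p of 0.0121 and 0.031. These 2 were called over all rows and adjusted over the list alone, but over leading rows alone Ccng1 had an adjusted p of 0.0636. Trp53inp1 had 0.46 ± 0.184 and Phlda3 0.16 ± 0.065 in the authors' deposited table, neither of them called. The cell cycle inhibitor Cdkn1a, a main p53 target, stood at -0.01 in the authors' deposited table. This list too moved in a comparison in which the macrophage lists were lower and the pericyte list higher, with the limits given above.

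**Figure D4:**
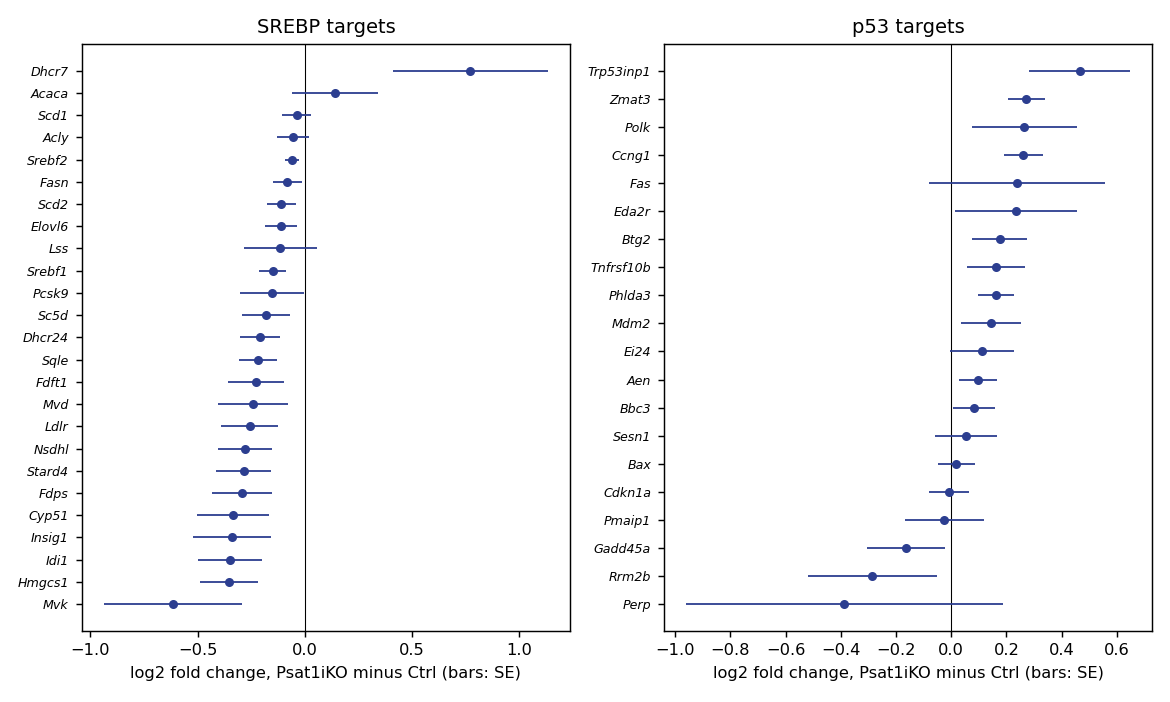
Log2 fold changes (Psat1iKO minus Ctrl) of the leading row of each measured member of the SREBP list (left, 25 of its 26 genes drawn) and the p53 list (right, 20 genes), with the authors' DESeq2 SE as bars and a line at 0. Of the SREBP targets drawn 23 lie under 0, and of the p53 targets 15 lie above 0.

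The glycolysis list had a limma cameraPR adjusted p of 0.0282 towards lower values, with Eno1 as its 1 called member of 22 and a median of -0.01. Without Eno1 and Eno1b the adjusted p was 0.726. Pfkp stood at -0.19 ± 0.0799 and Aldoa at 0.07 ± 0.0344 in the authors' deposited table, neither called. Nuclear genes of oxidative phosphorylation ranged from -0.08 to 0.08 over 56 members with 0 called (limma cameraPR adjusted p = 0.747). Glutamine and alpha-ketoglutarate genes had a median of -0.01 (25 members, 0 called, adjusted p = 0.801 by limma cameraPR). Targets of ATF4, which respond to amino acid shortage, had a median of -0.04 over 30 members with 0 called (limma cameraPR adjusted p = 0.551). Chac1, an ATF4 target that degrades glutathione, had -0.19 ± 0.12 in the authors' deposited table.

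Lists of proliferation and muscle differentiation did not pass the test. S phase genes had a median of -0.01 over 35 members (limma cameraPR adjusted p = 0.753) and G2/M genes 0.00 over 40 (0.979), with 0 called in either. The proliferation marker Mki67 had 0.22 ± 0.523 in the authors' deposited table. In the muscle stem cell and myoblast list, 19 of 25 members lay above 0 and Myod1 was called (limma cameraPR adjusted p = 0.256, 0.034 in the rank version and 0.0239 without Eno1 and Eno1b). Its leading row for Pax7, the stem cell transcription factor, had 0.07 ± 0.188 and Myf5 had 0.09 ± 0.156 in the authors' deposited table. Differentiation and fusion genes had a median of -0.07 over 28 members (limma cameraPR adjusted p = 0.575), and Myog, a factor of terminal differentiation, had -0.18 ± 0.32 in the authors' deposited table. Adult myofibre genes had a median of -0.05 over 37 members (limma cameraPR adjusted p = 0.81), with 1 minor row called, Tpm1.11. Denervation and atrophy genes had -0.06 over 19 (limma cameraPR adjusted p = 0.804).

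Markers of macrophages were lower and those of pericytes and smooth muscle were higher in Psat1iKO as groups. The median mean count was 84.6 and 59.95 in the macrophage lists and 230 in the pericyte list. A sort of muscle stem cells, which the labels name, would be meant to remove these cell types, so what their markers stand for here is unsettled. Their medians are low beside the 2057 of muscle stem cell and myoblast genes. The shifts are therefore not read here as a change in the cell composition of whole muscle. Monocyte and inflammatory macrophage markers had a median log2 fold change of -1.36, with 20 of 24 under 0 (limma cameraPR adjusted p = 0.00815). Resident and repair macrophage markers had -0.83, with 21 of 25 under 0 (adjusted p = 0.00815 by limma cameraPR). No member was called in either (0 of 24 and 0 of 25), also when adjusted over the list alone, and 5 and 2 were lower at an unadjusted p under 0.05. Il1b, an inflammatory cytokine, had -2.22 ± 0.901 and Cd14, a receptor for bacterial lipid, -2.15 ± 0.97 in the authors' deposited table. Trem2 had -2.79 ± 1.34 and the complement gene C1qb -2.00 ± 1.07 in the authors' deposited table, on mean counts of 39.0 and 101. Pericyte and smooth muscle markers had a median of 0.69, with 13 of 18 above 0 (limma cameraPR adjusted p = 0.0115). Rgs5 had 1.04 ± 0.352 and Myl9 0.55 ± 0.281 in the authors' deposited table, with 0 leading rows and the minor row Myh11.2 called. At a preset correlation of 0.05 the adjusted p was 0.0798 for each of these 3 lists. Restricted to a mean of at least 100, which left 12, 9 and 11 members and kept Eno1b, it was 0.483, 0.607 and 0.174. Without Eno1 and Eno1b and with no limit on the mean, limma cameraPR gave 8.11e-06 for both macrophage lists and 2.02e-05 for the pericyte list.

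Other cell type lists did not pass the test. Neutrophil markers had a median of -1.31 over 10 members (limma cameraPR adjusted p = 0.283, and 0.0433 without Eno1 and Eno1b). The median was -0.28 for dendritic cell genes over 14 members (limma cameraPR adjusted p = 0.581) and -0.50 for endothelial genes over 21 (0.668). T and NK cell genes had 0.07 over 8 (limma cameraPR adjusted p = 0.981), erythroid genes 0.04 over 8 (0.981) and adipocyte genes -0.06 over 10 (0.628). For B cells 3 members were measured, too few for the test, with a median of 0.18. Tenocyte markers had 0.69 over 10 (limma cameraPR adjusted p = 0.283, 0.0104 in the rank version and 0.0374 without Eno1 and Eno1b). Schwann cell genes had 0.03 over 16 (limma cameraPR adjusted p = 0.81), with a minor row of Pmp22 called. Fibro-adipogenic progenitor and fibroblast markers had 0.14 over 27 (limma cameraPR adjusted p = 0.628), and extracellular matrix genes 0.06 over 36 (0.551). Adjusted over the list alone, the first of these had 1 member higher and 2 lower, and the second 1 lower. Col5a1 had -0.67 ± 0.207, Fbn1 -0.31 ± 0.105 and Col15a1 1.94 ± 0.691 in the authors' deposited table, none called over all rows. Interferon response genes had 0.15 over 30 members (limma cameraPR adjusted p = 0.753), and immediate early genes of sample handling 0.02 over 20 (0.795). Hspa1a, a heat shock gene of the latter, had 0.52 ± 0.228 in the authors' deposited table.

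The deposited enrichment lists rest on the rows past 2-fold. The list for rows higher in Psat1iKO has 21 terms and that for lower rows 84, and all have an unadjusted p under 0.05. At a q under 0.05 there are 0 terms in either, with lowest q of 1 and 0.232 in the authors' deposited table. Negative regulation of axonogenesis led the higher list in the authors' deposited table (p = 0.000193), through Sema6c, Tsc2, Ulk1 and Sema4g. Gene expression led the lower list in the authors' deposited table (p = 3.15e-05), followed by RNA polymerase II transcription and muscle tissue development (p = 4.82e-05). Mtor or Tsc1 counts in 55 of the 84 lower terms, through the minor rows described above. Of 27 genes in the higher list, 26 had a called row in that direction, 4 had a called leading row, and Eno1b alone had a 2-fold gene total. Of 48 genes in the lower list these numbers were 46, 3 and 1 (Tlr3). Egr1 counts in 39 of the 84 lower terms, but its 1 row had a log2 fold change of 0.22 ± 0.32 in the authors' deposited table. Gene numbers in the lower list matched 0 of 48 mouse genes, against 26 of 27 in the higher list, and 10 lower terms carry rat codes.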

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

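Settings named here as leading rows alone, without the chromosome 4 window, 2-fold gene totals, a preset correlation of 0.2, every row of each gene and without Eno1 and Eno1b were chosen after seeing the data. From 241 called rows, the count went to 145 at an adjusted p under 0.01, 85 with a mean of at least 100 and 37 for leading rows alone, with fewer rows tested in the last pair. The 177 rows past 2-fold went to 110, 26 and 11 under the same settings. They went to 9 where the summed rows of the gene also had to change 2-fold, which genes with 1 row meet by definition. At an adjusted p under 0.1 the counts were 357 and 255, and without genes within 20 Mb of Pax7 they were 218 and 172. Psat1 kept its call at both other thresholds, with the adjustment recomputed over every row, with a mean of at least 100 and over leading rows alone, with adjusted p from 9.58e-10 to 1.37e-09. The 6 shifted lists became 1 at a preset correlation of 0.05, 0 at 0.2 and 2 with a mean of at least 100, where 22 of the 28 lists kept enough members to be tested. The count was 6 at a preset of 0, 7 in the rank version, 5 with every row of each gene and 8 without Eno1 and Eno1b. The SREBP list alone passed at 0.05, and SREBP and p53 targets passed with a mean of at least 100. The muscle stem cell and tenocyte lists passed in the rank version and without Eno1 and Eno1b, and the glycolysis list in neither. Neutrophil markers passed without Eno1 and Eno1b (adjusted p = 0.0433). In that setting limma cameraPR gave a smaller p for every list but glycolysis, with 3.01e-14 against 3.28e-07 for SREBP targets. The main list p-values, and which lists did not pass, thus depend in part on Eno1b. A higher preset widens the error of a list by construction. With a mean of at least 100 the macrophage lists kept 12 of 24 and 9 of 25 members and the pericyte list 11 of 18, and beyond this the cause was not tested. No list that passed in any of these settings changed direction. The inter-gene correlation itself was not estimated, since that needs values per library. Deposited terms at a q under 0.01 were 0, as at 0.05. Of the other named rows, 10 lost their call at an adjusted p under 0.01, 3 with a mean of at least 100 and 5 for leading rows alone, and 1 gained it at 0.1. No paired analysis was possible because the deposited comparison carries no values per library. For the same reason other normalizations, DESeq2 against edgeR, pseudocounts, leaving out a library and other splits of the libraries were not run, and depth per library is unknown. In simulated rows with the deposited errors, 40.1% of changes of 0.5 on the log2 scale and 64.8% of changes of 1 were recovered, so uncalled rows with wide errors may still differ by such sizes. Of leading rows with a mean of at least 100, 92.6% have a 95% interval that excludes a 2-fold change.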

Other observations

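Tests of the chromosome 4 segment, of its copy number, of Eno1 and Eno1b and of whole-gene change for minor rows were chosen after the values they use had been seen. The draws matched on mean count and the test of the other rows of a gene were fixed before they were run. Other splits of the libraries could not be counted without values per library.

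Sex-linked genes had wide errors of the fold change, and what made them wide was not tested. In the authors' deposited table, Xist had a log2 fold change of 0.36 ± 2.2, Ddx3y 0.13 ± 1.64, Eif2s3y -0.09 ± 2.13 and Kdm5d -0.17 ± 1.77. The median SE of leading rows with a mean of at least 100 was 0.113. Among leading rows called over leading rows alone, named here after their values were seen, Strn4 (0.21 ± 0.0427), Cdc27 (-0.32 ± 0.0756), Kirrel (0.54 ± 0.136) and Xpnpep1 (0.61 ± 0.128) had mean normalized counts of 2835, 2038, 2377 and 605 in the authors' deposited table.

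Genes called over leading rows alone were concentrated near Pax7 on chromosome 4, in both directions. The 10 Mb interval with the most called genes was 140 to 150 Mb on this chromosome (8 of 96 genes), and no interval on another chromosome held more than 2. Higher depth of these genes was argued against, since in 10000 draws of genes from elsewhere matched on mean count the highest number called was 5, against 15 observed. Gain or loss of a copy of the segment would shift all its genes one way, but the median log2 fold change of the 296 genes with a mean of at least 100 was -0.0188. A hypothesis that stays open is a linked segment of different strain origin in the groups, such as DNA that flanks an engineered allele; the driver of the knockout is not named in the labels. Genes of the window not called over leading rows alone passed an unadjusted p of 0.05 in 8.50% of 459 cases. Elsewhere the share was 3.74% of 15981, an odds ratio of 2.39 (95% interval 1.66 to 3.36). The excess goes with this hypothesis, though such genes can still be called over all rows. An effect of Psat1 loss on these genes was not tested.

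For Eno1b, reads of Eno1 assigned to its near-identical copy are a candidate explanation. The summed fitted means changed by -0.0339 on the log2 scale and the transcripts are 99.5% identical. Eno1 lies within the chromosome 4 window above, and a sequence variant there may move its reads to the copy on chromosome 18; no reads were examined, so this variant was not tested. A true switch between the genes by equal amounts was not tested either.

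For the rows past 2-fold in genes with several rows, a change of the whole gene is argued against: the summed rows changed 2-fold for 1.75% of the 171 rows. The median size of the change was 7.47 on the log2 scale for the row and 0.08 for the gene total. Taking the called row of smallest p per gene, the other rows of the gene, summed, moved the opposite way in 127 of 165 genes (77.0%, exact binomial 95% interval 69.8% to 83.2%). This is consistent with reads being divided differently among rows of 1 gene. For single genes it is not resolved, since the SE of the other rows was 1.62 times the change of the called row in the median. A change in isoform use and an unstable division of shared reads by the counting program would both give this. Which of them applies was not tested.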
